A study of Mus musculus with 18 samples.

How the data were processed

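RNA was measured in dissected cortical tissue of C57BL/6 mouse embryos at embryonic day 12.5, in 18 sequencing libraries from 4 genotypes. There were 4 wild-type (WT) libraries, 5 of Dmrt3 knockout (KO), 4 of Dmrt5 KO and 5 of the Dmrt3;Dmrt5 double KO. The gene called Dmrt5 in the labels has the current symbol Dmrta2, which is used for its transcript. Per the labels' protocols, RNA was purified with RNeasy columns and libraries were made with the TruSeq RNA Sample Prep Kit v2, a kit that does not mark the strand of a transcript. Reads from genes that overlap on opposite strands can therefore not be separated.

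The deposited files hold 1 raw read count per Ensembl gene and library, with no normalisation applied by the authors. Per the submitters' processing notes, bcl2fastq, CASAVA 1.8.2, FastQC 0.10.1, STAR 2.3.0e, featureCounts 1.4.6-p1 and DESeq2 1.8.2 were used with the mouse build mm10, without a statement of which step each tool performed. The annotation release behind the counts, the strand setting and the handling of reads that match several genes are not given in the sources used here, so values of pseudogenes and close paralogs are uncertain. Each file listed 38355 genes and 5 summary entries, and the summary entries were 0 throughout. Symbols and coordinates were taken from GENCODE M21 (GRCm38, the same assembly as mm10) by gene identifier. The identifiers matched for 36602 genes, and the unmatched ones held 0.397% of the counts. Total counts per library ran from 19602718 to 33072896.

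Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr for the 4 genotypes, which left 16236 genes. Libraries were scaled by the trimmed mean of M-values, and a quasi-likelihood model with 1 mean per genotype was fitted to all 18 libraries. Normalised read counts (CPM) were computed here from the deposited counts and these scaling factors, and levels are given as mean ± SD over the libraries of a genotype. Fold changes are those of the fitted model; log2 CPM values for scores of libraries and correlations were made with a prior count of 2. The standard error (SE) of a log2 fold change was taken from the fold change and the F statistic of its two-sided test. The p-values were adjusted over all tested genes with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. With no change in any gene, a share of about 0.05 of the 16236 tested genes would have an unadjusted p under 0.05. A gene is said to rise or fall only when it was called. The 6 comparisons were each KO against WT, the double KO against each single KO, and the interaction, defined as the double KO value minus both single KO values plus the WT value on the log2 scale. A negative interaction means that the double KO lay below the sum of both single KO effects. The labels do not state whether the libraries came from separate embryos or litters, so each p-value measures the spread between these libraries. Embryo sex was inferred from Xist and Y-linked transcripts, and each genotype held both sexes, in unequal numbers. WT held 2 male and 2 female libraries, Dmrt3 KO 3 and 2, Dmrt5 KO 3 and 1, and the double KO 2 and 3.

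Genes named in the text were chosen by a rule. It named Dmrt3, Dmrta2, Dmrta1 and 12 regulators of telencephalic patterning in every comparison. It also named up to 10 called genes per direction with the largest fold change, among genes with a mean log2 CPM of at least 1 and no overlap between the libraries of the genotypes compared. For genes named by this part of the rule, a lack of overlap is a condition of naming and not a further result. From each gene list it named up to 4 members with the lowest adjusted p. The 21 lists held markers of the cortical hem, Wnt targets, choroid plexus, Cajal-Retzius neurons, pallial progenitors, the glutamatergic lineage, the subpallium (lateral ganglionic eminence and GABAergic lineage), the medial ganglionic eminence, the antihem, rostral Fgf signalling, Notch signalling, the cell cycle, p53 targets, the diencephalon, the eye, mesenchyme, endothelium, microglia, erythroid cells, surface ectoderm and immediate early genes. Each list was tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 21 lists of a comparison, and again with a correlation estimated from the data and with fry. Counts of called members are given over all genes and adjusted over the list alone. The list members Gdf7, Kl, Cldn2, Tyr, Cryaa, Crygs, Trp63 and Fosb were not among the tested genes. The groups, comparisons, lists, rule for names, thresholds and first set of other settings were chosen before the data were examined.

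The fitting steps were tested on simulated data with 50 genes changed at each fold, drawn from the real means and library sizes. In the simulated Dmrt3 KO against WT, 12% of genes changed 1.5-fold, 58% changed 2-fold, 86% changed 3-fold and 96% changed 4-fold were called. For Dmrt5 KO against WT these shares were 6%, 52%, 82% and 86%, and for the double KO against WT they were 26%, 66%, 96% and 92%. For the double KO against Dmrt5 KO they were 6%, 52%, 80% and 92%, and against Dmrt3 KO 22%, 68%, 90% and 98%. For the interaction they were 2%, 28%, 62% and 78%. Between 3 and 6 unchanged genes were called per simulated comparison. A simulated shifted list gave a camera p of 5.8e-18, and 1 of 100 unshifted lists passed in the double KO against WT. The simulated genes varied independently of each other, so this does not test the list p-values where members of a list vary together.

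The other settings chosen then were the DESeq2 1.42.0 Wald test, normalisation by relative log expression (RLE), no filter on low counts, a filter of 1 CPM in 4 libraries, a fit of only the genotypes compared, the replicate number as a block, sex as a factor, an adjusted p under 0.01, a test against a 1.2-fold change, list tests with other assumptions, WT libraries divided between comparisons, and each library left out in turn. Chosen after seeing the data were covariates for each library's slope of expression against gene length, for its mesenchyme score, and for both, and fits without the 2 libraries that carried transcripts of both sexes or without the library highest in mesenchyme of each genotype. Correlations of fold changes between comparisons were set against 20 simulations in which both comparisons shared the WT libraries and no gene changed. Correlations and shared calls were also set against the 3 ways of dividing the WT libraries into parts of 2. The called counts were compared with other splits of the libraries, at most 100 per comparison. No tested library was left out of the values reported. Files of aligned reads were not analysed here.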

Results

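Transcript levels of whole dissected cortical tissue were compared between mouse embryos with and without the doublesex-related transcription factors Dmrt3 and Dmrt5. The 18 libraries comprised 4 of WT, 5 of Dmrt3 KO, 4 of Dmrt5 KO and 5 of the double KO, and held between 19602718 and 33072896 counts each. The design asks which genes each factor affects alone, and which change only when both are missing.

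The targeted transcripts were read first. Dmrt3 (ENSMUSG00000042372, mm10 chromosome 19, 25610301 to 25623921) stood at 56.9 ± 4.1 CPM in WT (SD, n = 4), 0.308 ± 0.0654 in Dmrt3 KO (n = 5), 41.5 ± 7.97 in Dmrt5 KO (n = 4) and 0.157 ± 0.18 in the double KO (n = 5). The double KO libraries held 0, 0, 2, 8 and 9 counts of Dmrt3. Dmrta2 (ENSMUSG00000047143, chromosome 4, 109978053 to 109983687) stood at 194 ± 29.7 CPM in WT, 219 ± 53.7 in Dmrt3 KO, 10.7 ± 9.64 in Dmrt5 KO and 3.55 ± 1.34 in the double KO. Within Dmrt5 KO, 3 libraries held 4.31, 6.57 and 6.94 CPM of Dmrta2, and replicate 1 held 25.07 CPM from 507 counts. Every library lacking a factor by its label was thus below every WT library for that factor's transcript. The counts are summed over the whole gene, so transcript from an undeleted part of a targeted allele is included. The related gene Dmrta1 (ENSMUSG00000043753, chromosome 4, 89679436 to 89694772) was not called against WT, with log2 fold changes of 0.22 in Dmrt3 KO, 0.39 in Dmrt5 KO and 0.22 in the double KO (adjusted p 0.671, 0.495 and 0.659).

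**Figure D1:**
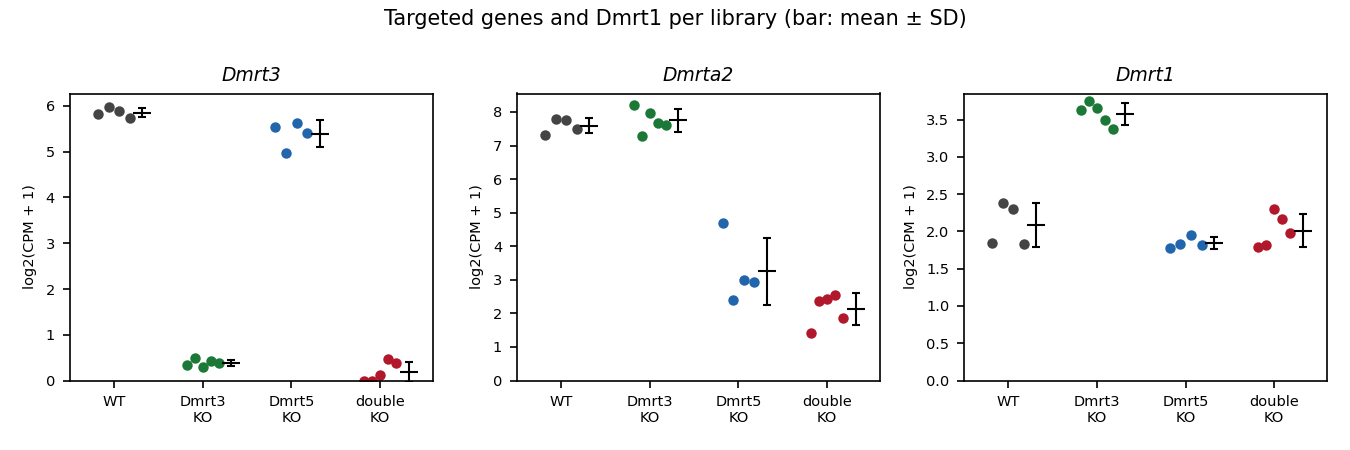
Level, as log2(CPM + 1), of Dmrt3, Dmrta2 and Dmrt1 in each of the 18 libraries (points), by genotype, with bars for mean ± SD. Dmrt3 is near 0 in both genotypes with the Dmrt3 KO, and Dmrta2 is 25.07 CPM in 1 Dmrt5 KO library and at most 6.94 CPM in the other 3.

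No regulator of telencephalic patterning was called after loss of Dmrt3 alone. The pallial regulators Emx1 and Emx2 had log2 fold changes of 0.14 and -0.20, Pax6 0.23 and the subpallial regulator Gsx2 0.10 in Dmrt3 KO against WT (adjusted p 0.791, 0.671, 0.652 and 0.835). Larger uncalled values were 0.61 for Dbx1, -0.55 for Wnt8b and -0.48 for Gli3 (adjusted p 0.616, 0.65 and 0.65). With edgeR 1 gene rose and 1 fell among the 16236 tested, while 1163 genes had an unadjusted p under 0.05. DESeq2 called 1 gene higher and 53 lower. Dmrt3 itself fell by 7.51 on the log2 scale (SE 0.41, adjusted p = 1.13e-08). The gene that rose was Dmrt1, which lies beside Dmrt3 (ENSMUSG00000024837, chromosome 19, 25505618 to 25604329, starting 105 kb away). Dmrt1 stood at 3.32 ± 0.879 CPM in WT and 11 ± 1.21 in Dmrt3 KO, a 3.33-fold rise (log2 1.73 ± 0.19 SE, adjusted p = 0.000553) with all 5 libraries above the 4 WT libraries. It was 3.06 ± 0.635 CPM in the double KO. Without WT replicate 2 or WT replicate 4 the number of genes lower in Dmrt3 KO was 5 or 3. With the gene length slope of each library as a covariate, chosen after seeing the data, it was 51.

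Of 17 genes of the cortical hem, the dorsal midline source of Wnt and Bmp signals, none was called in Dmrt3 KO by edgeR; 12 had values below WT and 5 above (log2 0.07 to 0.38). Wnt3a stood at 13.7 ± 2.06 CPM in WT and 8.06 ± 0.963 in Dmrt3 KO, a log2 fold change of -0.76 ± 0.45 (SE, adjusted p = 0.65). Lmx1a stood at 18.9 ± 1.26 and 13.1 ± 1.72 CPM (log2 -0.53, adjusted p = 0.65). Lhx2, from the pallial progenitor list, stood at 755 ± 50.1 and 601 ± 55.2 CPM (log2 -0.33 ± 0.11, adjusted p = 0.558). For these 3 uncalled genes all 5 Dmrt3 KO libraries were below all 4 WT libraries. Such a lack of overlap also arises by chance, and its frequency over all genes was not counted, so it does not show a fall. As a list, cortical hem genes had a median log2 fold change of -0.47 (camera adjusted p = 0.0258), and adjusted p = 0.974 with an estimated correlation. Diencephalon and microglia markers had medians of 0.59 and 0.54 (adjusted p 0.0292 and 0.0258), each with adjusted p = 0.974 with an estimated correlation. In these 3 lists no member was called by edgeR, over all genes or adjusted over the list alone; examples are Irx1 (log2 1.78), Nkx2-2 (2.59), Tyrobp (0.81) and C1qb (0.72), each with adjusted p = 0.65. The values of Irx1 and Nkx2-2 rest on Dmrt3 KO replicate 2, with 6.32 and 3.31 CPM against at most 0.83 and 0.77 in the other 4 Dmrt3 KO libraries, and were 0.37 and 0.82 without it (adjusted p 0.84 and 0.833). The hem call was lost without WT replicate 2 or Dmrt3 KO replicates 2 or 4 (adjusted p 0.0684 to 0.369). The diencephalon call was lost without WT replicates 1, 2 or 3 or Dmrt3 KO replicates 2 or 3 (0.0567 to 0.492), and the microglia call without WT replicates 2 or 3 or Dmrt3 KO replicate 5 (0.0567 to 0.205). The other 18 lists had camera adjusted p between 0.14 and 0.937, with 1 surface ectoderm gene lower when adjusted over the list alone. The subpallial list (median 0.11, adjusted p = 0.14) passed without WT replicate 3 or Dmrt3 KO replicates 1 or 5 (0.0154 to 0.0345; median 0.15 each time), and the medial ganglionic eminence list (0.35, 0.47) without Dmrt3 KO replicate 4 (0.55, 0.0384). Among the 18 the glutamatergic, antihem, rostral Fgf, Notch and mesenchyme lists had medians, means and tests of differing sign.

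Loss of Dmrt5 alone lowered genes of the dorsal midline and of the pallium and raised genes of the subpallium. Ttr (chromosome 18, 20665280 to 20674321), the main transcript of choroid plexus epithelium, fell from 152 ± 82.9 CPM in WT (SD, n = 4) to 5.47 ± 3.75 in Dmrt5 KO (n = 4), 27.6-fold (adjusted p = 0.00934). The hem regulator Lmx1a (chromosome 1, 167689237 to 167848741) fell from 18.9 ± 1.26 to 5.08 ± 0.278 CPM, 3.72-fold (log2 -1.90 ± 0.24 SE, adjusted p = 0.001). The selector gene Lhx2 (chromosome 2, 38339281 to 38369733) fell from 755 ± 50.1 to 355 ± 24.9 CPM, 2.13-fold (log2 -1.09 ± 0.12, adjusted p = 0.000177). Of subpallial genes, Six3 (chromosome 17, 85613608 to 85629302) rose from 56.5 ± 7.12 to 114 ± 9.31 CPM, 2.01-fold (adjusted p = 0.000862), and Dlx2 (chromosome 2, 71543408 to 71546754) from 168 ± 31.2 to 356 ± 37.5 CPM, 2.11-fold (adjusted p = 0.0078). In each of these 5 genes the 4 Dmrt5 KO libraries did not overlap the 4 WT libraries. Over all genes 55 rose and 112 fell, of which 23 and 93 changed more than 2-fold, and 1835 genes had an unadjusted p under 0.05. Other genes with large falls include the choroid plexus channel subunit Kcne2 (log2 -4.70), Dct (-3.05 ± 0.29, adjusted p = 5.15e-05), Fam129a (-2.63) and Rbm20 (-2.59). The pallial regulator Fezf2 fell from 113 ± 10.8 to 59.8 ± 8.28 CPM (log2 -0.92 ± 0.13, adjusted p = 0.00364), and the Notch target Hey1 fell by 0.67 on the log2 scale (adjusted p = 0.00733). Among genes with the largest rises were Gpr83 (log2 1.90), Stac2 (1.37), Slc30a3 (1.28) and Slc10a4 (1.24); BC002163, a processed pseudogene for which reads of a parent gene cannot be excluded, had a log2 fold change of 3.32, and of 4.05 without WT replicate 2.

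The counts of this comparison depended on the method and on single libraries. DESeq2 called 210 genes higher and 228 lower, and edgeR 215 and 276 with the length slope as a covariate, against 55 and 112. The numbers higher and lower are thus closer to each other with these methods. Without single libraries the count of genes higher ran from 14 without Dmrt5 KO replicate 2, the 1 female library of this genotype, to 55. That count was 22 without WT replicate 1, 25 without WT replicate 3, 17 without WT replicate 4, and 22, 29 and 16 without Dmrt5 KO replicates 1, 4 and 5. The count of genes lower was 68, 170 and 66 without WT replicates 1, 2 and 4, and 56, 40, 71 and 56 without Dmrt5 KO replicates 1, 2, 4 and 5. Emx2 stood at 206 ± 38.8 CPM in WT and 118 ± 10.6 in Dmrt5 KO (log2 -0.80 ± 0.18, adjusted p = 0.0404), and its call held only without WT replicate 4 (0.0663 to 0.154 without each of the other 7). Tyrosine hydroxylase (Th, log2 1.55) and Foxj1 (-1.17) lost their calls without Dmrt5 KO replicate 2 (adjusted p 0.056 and 0.0613). Wnt2b had a log2 fold change of -3.09 and Sp5 of -1.80; Wnt2b was called only without WT replicate 2 or 3 (otherwise 0.0506 to 0.135) and Sp5 only without WT replicate 1 or 2 (otherwise 0.0514 to 0.117). Genes that did not pass include Emx1 (73.6 ± 21.6 CPM against 153 ± 32.5, log2 -1.05 ± 0.26, adjusted p = 0.0603), Gsx2 (0.87, 0.082), Wnt3a (-1.90, 0.0901), Pax6 (0.57, 0.111), Gli3 (-0.62, 0.205), Wnt8b (-0.73, 0.391), Dbx1 (0.41, 0.534) and Neurog2 (-0.22, 0.673). Emx1 passed without Dmrt5 KO replicate 1 (adjusted p = 0.0419) and Gsx2 without WT replicate 3 (0.045).

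By list in Dmrt5 KO, 7 of 20 subpallial members rose and 0 fell, with 17 higher when adjusted over the list alone. Their median log2 fold change was 0.91 (camera adjusted p = 9.61e-29, and 0.00285 with an estimated correlation). Of 9 choroid plexus members 6 fell, 7 when adjusted over the list alone (median -1.96, adjusted p = 1.49e-14, and 0.00155 with an estimated correlation). Of 14 pallial progenitor members 4 fell, and 7 fell and 2 rose when adjusted over the list alone (median -0.34, adjusted p = 3.27e-05, and 0.0463 with an estimated correlation). Of 6 genes of the medial ganglionic eminence none was called over all genes by edgeR and 6 rose when adjusted over the list alone, such as Lhx8 (log2 1.5) and Lhx6 (1.38); their median was 1.44 (adjusted p = 3.48e-10, and 0.0463 with an estimated correlation). Of 17 cortical hem genes 2 fell, 9 when adjusted over the list alone (median -1.11, adjusted p = 2.74e-14), and the list had adjusted p = 0.0551 with an estimated correlation. Of 14 Wnt targets 2 fell, 6 when adjusted over the list alone (median -0.68, adjusted p = 1.27e-06), with adjusted p = 0.135 with an estimated correlation. Rostral Fgf genes had a median of 0.34 (adjusted p = 0.00266) and adjusted p = 0.442 with an estimated correlation. The glutamatergic lineage had 1 of 14 members higher over all genes, Neurod4 (log2 1.30, called without WT replicate 2 and otherwise at 0.0573 to 0.0992), and 1 higher and 3 lower when adjusted over the list alone. It had a median of -0.35 (adjusted p = 0.0202), and adjusted p = 0.607 with an estimated correlation; its call was lost without WT replicates 1 or 4 or Dmrt5 KO replicates 2 or 4 (0.0516 to 0.216). Diencephalon markers had a median of 0.51 and surface ectoderm markers of -0.90 (adjusted p 0.0194 and 0.0277), with adjusted p = 0.442 and 0.607 with an estimated correlation. The diencephalon call was lost without WT replicates 1 or 2 or Dmrt5 KO replicate 5 (0.0635 to 0.0997), the ectoderm call without WT replicates 2 or 3 or Dmrt5 KO replicate 5 (0.128 to 0.328). Eye markers had a median of 0.49 but a mean of -0.15, and the test called them lower (adjusted p = 0.0202, and 0.135 with an estimated correlation), without WT replicate 2 or Dmrt5 KO replicate 5 not (0.0928 to 0.0997). Mesenchyme and endothelium had medians of -0.51 and -0.23 (adjusted p 0.0999 and 0.182), with mesenchyme passing without Dmrt5 KO replicate 4 (adjusted p = 0.0041), and the 8 lists not given here had adjusted p between 0.0968 and 0.934, the p53 and microglia lists among them with medians and means of opposite sign. Of these 8, the cell cycle and erythroid lists passed without WT replicates 1 or 4 (0.00829 to 0.0361), and the antihem list without WT replicate 4 or Dmrt5 KO replicate 1 (0.00405 to 0.0265).

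**Figure D2:**
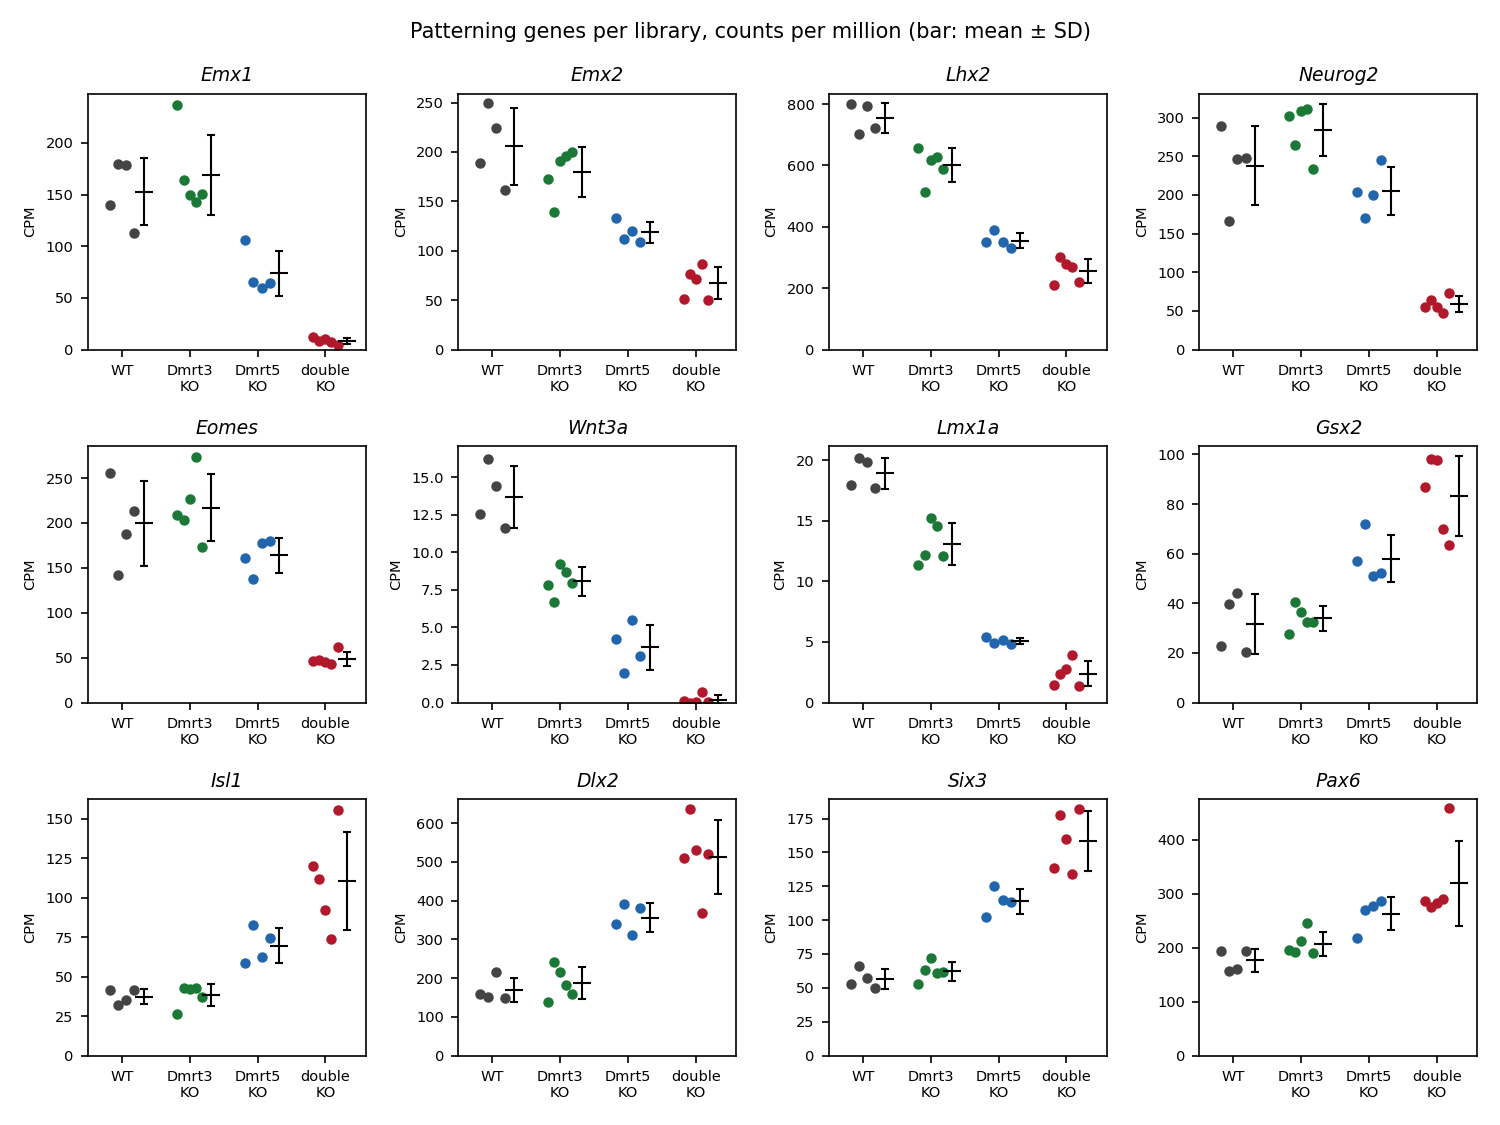
Normalised level (CPM, linear axes from 0) of 12 patterning genes in each library (points), by genotype, with bars for mean ± SD. Lhx2 falls from 755 CPM in WT to 355 in Dmrt5 KO and 257 in the double KO, and Neurog2 is 204 CPM in Dmrt5 KO and 58.9 in the double KO.

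Loss of both factors lowered genes of dorsal pallial progenitors and of the glutamatergic lineage, and raised subpallial genes. The pallial regulator Emx1 (chromosome 6, 85187438 to 85204462) fell from 153 ± 32.5 CPM in WT (SD, n = 4) to 8.51 ± 2.86 in the double KO (n = 5), 18-fold (log2 -4.17 ± 0.27 SE, adjusted p = 3.16e-08). The proneural gene Neurog2 (chromosome 3, 127633135 to 127635631) fell from 238 ± 51.3 to 58.9 ± 9.86 CPM, 4.03-fold (adjusted p = 5.18e-07). Eomes (chromosome 9, 118478212 to 118486132), which marks intermediate progenitors, fell from 200 ± 47.3 to 48.7 ± 7.84 CPM, 4.1-fold (adjusted p = 6.63e-07), and Neurod6 (chromosome 6, 55677822 to 55681263) from 99.4 ± 61.7 to 2 ± 2.27 CPM, 50.5-fold (adjusted p = 1.55e-05). Neurod6 was 6.02 CPM in double KO replicate 1 and 0.64 to 1.48 in the other 4, and fell 99.2-fold without that library. In the other direction Gsx2 (chromosome 5, 75075601 to 75077893) rose from 31.7 ± 11.9 to 83.3 ± 16 CPM, 2.63-fold (adjusted p = 0.000716), and Dlx2 from 168 ± 31.2 to 513 ± 95.7 CPM, 3.04-fold (adjusted p = 2.59e-05). In each of these 6 genes the 5 double KO libraries lay outside the range of the 4 WT libraries. Over all genes 393 rose and 619 fell, 182 and 510 of them by more than 2-fold, and 2869 genes had an unadjusted p under 0.05. The count of genes higher was 252 without WT replicate 3, and the counts higher and lower were 734 and 1272 without double KO replicate 4. They were 1052 and 1243 with the length slope as a covariate, 145 and 330 with the mesenchyme score and 131 and 237 with only these 2 genotypes in the fit. DESeq2 called 656 higher.

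Of 14 pallial progenitor members 9 fell and 1 rose in the double KO, and 11 fell and 1 rose when adjusted over the list alone (median log2 fold change -1.31, camera adjusted p = 4.82e-33, and 1.77e-05 with an estimated correlation). Beside Emx1 and Neurog2 they include Lhx2 (755 ± 50.1 to 257 ± 39.1 CPM, 2.94-fold), Emx2 (chromosome 19, 59458372 to 59465357; 206 ± 38.8 to 67 ± 16.1 CPM, 3.07-fold) and Fezf2 (chromosome 14, 12342094 to 12348189; 113 ± 10.8 to 28 ± 3.8 CPM, 4.04-fold). Pax6 (chromosome 2, 105668900 to 105697364) was the member that rose, from 176 ± 20.8 to 319 ± 78.7 CPM (1.81-fold, adjusted p = 0.00208). Of 14 glutamatergic lineage members 8 fell, 9 when adjusted over the list alone, such as Nhlh1 (5.48-fold), Neurod1 (4.6-fold) and Slc17a7 (11-fold); the median was -1.49 (adjusted p = 1.67e-28, and 0.00412 with an estimated correlation). Of 20 subpallial members 17 rose and 0 fell, 19 when adjusted over the list alone, with a median of 1.53 (adjusted p = 5.49e-38, and 0.000569 with an estimated correlation). They include Six3 (56.5 ± 7.12 to 158 ± 21.9 CPM, 2.8-fold) and Isl1 (37.4 ± 4.82 to 111 ± 31 CPM, 2.96-fold). Of 6 medial ganglionic eminence members 5 rose, 6 when adjusted over the list alone, such as Nkx2-1 (58.4 ± 17.2 to 234 ± 82.6 CPM, adjusted p = 0.0116) and Lhx8 (log2 2.07); the median was 1.90 (adjusted p = 6.9e-10, and 0.0301 with an estimated correlation).

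Midline genes also fell. Wnt3a (chromosome 11, 59248033 to 59290752) fell from 13.7 ± 2.06 to 0.181 ± 0.306 CPM, 72.7-fold (log2 -6.18 ± 0.60, adjusted p = 5.35e-06), and Lmx1a from 18.9 ± 1.26 to 2.36 ± 1.04 CPM, 7.99-fold. Without double KO replicate 4, which held 0.72 CPM of Wnt3a against 0 to 0.1 in the other 4, the Wnt3a fall was 277-fold. Rspo2, Rspo3 and Wnt8b fell 7.62-fold, 7.94-fold and 3.52-fold. Hem and mesenchyme scores were both highest in the same library of each genotype, such as double KO replicate 4 (hem 2.9, others 0.54 to 0.92; mesenchyme 6.26) and Dmrt5 KO replicate 4 (hem 3.24; mesenchyme 6.07). With the mesenchyme score as a covariate, chosen after seeing the data, Wnt3a had a log2 fold change of -5.58, Lmx1a of -2.72 and Rspo2 of -2.77 (adjusted p 3.26e-06, 4.71e-06 and 0.000165). Of 17 cortical hem members 11 fell, 12 when adjusted over the list alone (median -2.22, adjusted p = 7.58e-31, and 0.00315 with an estimated correlation). Of 14 Wnt targets 8 fell, 9 when adjusted over the list alone, such as Sp5 (19.6 ± 4.39 to 1.38 ± 0.908 CPM, 14.2-fold) and Tnfrsf19 (log2 -1.90); the median was -0.74 (adjusted p = 9.9e-11, and 0.0301 with an estimated correlation). Of 9 choroid plexus members 7 fell, and 7 fell and 1 rose when adjusted over the list alone (median -3.63, adjusted p = 5.14e-18, and 0.000464 with an estimated correlation); Ttr fell 121-fold to 1.29 ± 1.88 CPM, and 334-fold without double KO replicate 1, which held 4.65 CPM against 0.2 to 0.64 in the other 4. Of 10 Cajal-Retzius members Trp73 (40.8 ± 11.4 to 10.6 ± 2.25 CPM, 3.87-fold) and Ebf2 (4.37-fold) fell and Lhx5 rose (log2 1.07 ± 0.23, adjusted p = 0.00664), also when adjusted over the list alone. The list had a median of 0 and camera adjusted p = 0.0837, and was called lower without WT replicate 2 (median -0.10, adjusted p = 0.0458) and without double KO replicate 5 (-0.21, 0.00429).

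Genes of other signalling systems changed in small numbers. Of 8 antihem members Sfrp2 rose (log2 1.12 ± 0.19, adjusted p = 0.00111) and Dbx1 fell (7.67 ± 1.24 to 3.6 ± 1.13 CPM, 2.13-fold, adjusted p = 0.00534), with 4 higher and 2 lower when adjusted over the list alone (median 0.39, list adjusted p = 0.283). Of 13 rostral Fgf members Fgf15 (log2 1.16 ± 0.26, adjusted p = 0.0109) and Sp8 (0.77, adjusted p = 0.0334) rose, 4 when adjusted over the list alone (median 0.39, list adjusted p = 0.00392, with adjusted p = 0.414 with an estimated correlation); the list call was lost without double KO replicate 4 (0.0862). The Sp8 call was lost without WT replicates 1, 3 or 4 or double KO replicates 1 or 5 (0.056 to 0.111). Of 11 Notch members Dll3 rose and Hey1 fell (log2 0.70 and -0.91), with 1 higher and 4 lower when adjusted over the list alone (median -0.06, adjusted p = 0.216). The Dll3 call was lost without WT replicates 1, 2 or 4 or double KO replicates 1, 2 or 3 (0.0513 to 0.131). Of 20 cell cycle genes none was called by edgeR, with a median of -0.06 (adjusted p = 0.35). Of 13 p53 targets Cdkn1a fell (log2 -0.84, adjusted p = 0.0199), also the single member when adjusted over the list alone (median 0.05, list adjusted p = 0.878); its call was lost without WT replicates 2 or 3 (0.0617 to 0.0782). Of 9 immediate early genes Dusp1 rose by 0.51 and Egr1 fell by 1.15 on the log2 scale, and 1 rose and 2 fell when adjusted over the list alone (median -0.39, list adjusted p = 0.326). The Egr1 call held only without WT replicate 3 or double KO replicate 4 (otherwise 0.063 to 0.124). Gli3 was not called (log2 -0.56, adjusted p = 0.0935), but was without double KO replicate 5 (-0.74, 0.0111).

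Markers of tissues outside the cortex were measured in the same libraries. The mesenchyme list had a median of -0.90 (camera adjusted p = 0.000269) and adjusted p = 0.414 with an estimated correlation, with none of its 12 members called by edgeR. Col1a1 stood at 333 ± 279 CPM in WT and 102 ± 179 in the double KO (log2 -1.70, adjusted p = 0.456). It was called without double KO replicate 4 (log2 -3.89, adjusted p = 0.012), and had a log2 fold change of -0.94 without WT replicate 4 (adjusted p = 0.754). Endothelium had a median of -0.58 (adjusted p = 0.000318) and adjusted p = 0.262 with an estimated correlation. Erythroid genes had a median of -0.94 (adjusted p = 0.00836) and adjusted p = 0.414 with an estimated correlation, and the call was lost without WT replicates 2 or 3 or double KO replicate 5 (0.068 to 0.26). Eye markers had a median of 0.40 but a mean of -0.36, and the test called them lower (adjusted p = 0.0136, and 0.107 with an estimated correlation); Dct fell 34.8-fold and Mitf by 1.5 on the log2 scale. Diencephalon (median 0.33, with Gbx2 higher), microglia (-0.04) and surface ectoderm (-0.21, with Krt8 and Krt18 lower) had list adjusted p of 0.35, 0.423 and 0.134; surface ectoderm passed without WT replicate 1 (0.0303) or double KO replicate 4 (0.0145). The Gbx2 call was lost without WT replicates 1, 2 or 4 or double KO replicates 1, 2 or 3 (0.0624 to 0.0907), that of Krt18 without WT replicate 2 or double KO replicate 2 (0.0528 to 0.0877), and that of Krt8 without WT replicates 2 or 3 or double KO replicate 1 (0.0537 to 0.0869).

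**Figure D3:**
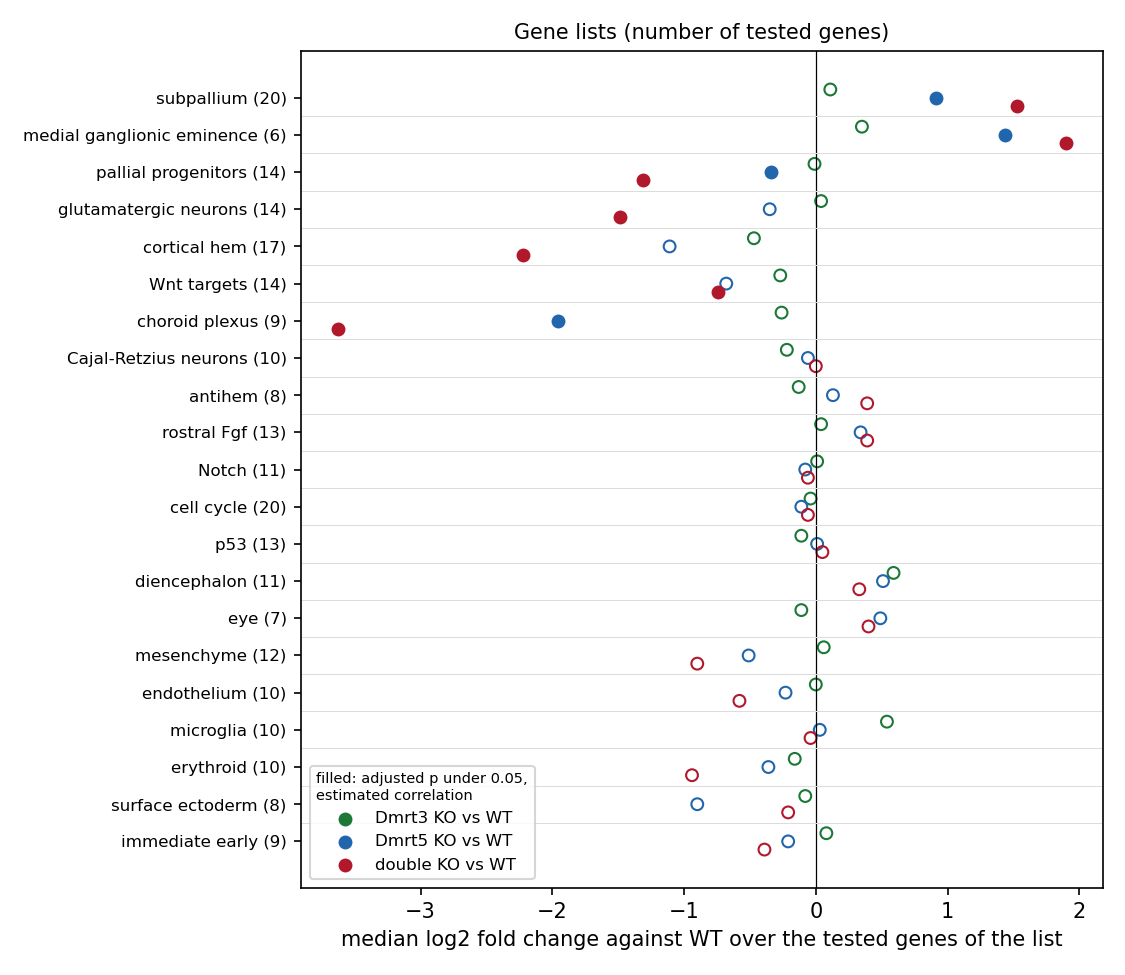
Median log2 fold change of each of the 21 gene lists in the 3 comparisons against WT, with filled points where the list passed with an estimated correlation (adjusted p under 0.05). Subpallial genes have medians of 0.91 in Dmrt5 KO and 1.53 in the double KO against WT, and the glutamatergic lineage has -0.35 and -1.49.

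In the double KO, genes of the glutamatergic lineage and pallial regulators were lower than in Dmrt5 KO. Emx1 fell from 73.6 ± 21.6 CPM (SD, n = 4) to 8.51 ± 2.86 (n = 5), 8.66-fold (log2 -3.11 ± 0.26 SE, adjusted p = 3.52e-06). Neurog2 fell from 204 ± 31 to 58.9 ± 9.86 CPM, 3.47-fold (adjusted p = 8.01e-06), and Eomes from 164 ± 19.6 to 48.7 ± 7.84 CPM, 3.37-fold (adjusted p = 1.53e-05). Neurod6 fell from 54.5 ± 17.5 to 2 ± 2.27 CPM, 27.7-fold (adjusted p = 0.000396), and 54.4-fold without double KO replicate 1. Tfap2c fell from 96.7 ± 14.1 to 32.3 ± 5.74 CPM, 2.99-fold (adjusted p = 3.5e-05), and its paralog Tfap2e by 2.24 on the log2 scale. The hem signal Wnt3a fell from 3.68 ± 1.5 to 0.181 ± 0.306 CPM, 19.5-fold (adjusted p = 0.00131; 74.5-fold without double KO replicate 4), Dbx1 2.84-fold and Fezf2 2.13-fold. In each of these genes the 5 double KO libraries were below the 4 Dmrt5 KO libraries. Over all genes 2 rose and 52 fell, 1 and 45 of them more than 2-fold, and 764 had an unadjusted p under 0.05, fewer than expected with no change in any gene. Without Dmrt5 KO replicate 4 the number of genes lower was 33, and 19 with only these 2 genotypes in the fit. DESeq2 called 13 higher and 99 lower, and edgeR 7 and 102 with the length slope as a covariate. Smoc1, 1 of the 2 genes that rose, went from 47.1 ± 2.33 to 79.3 ± 5.54 CPM (log2 0.75 ± 0.12, adjusted p = 0.00529). The other was Foxn4 (log2 1.66, adjusted p = 0.0488), named after its values were seen. Smoc1 kept its call without each of the 9 libraries, and it was the 1 gene higher, with Foxn4 no longer called, without Dmrt5 KO replicates 1, 2, 4 or 5 or double KO replicates 2, 3 or 5. Emx2 fell from 118 ± 10.6 to 67 ± 16.1 CPM (log2 -0.82 ± 0.17, adjusted p = 0.0434), with the call kept only without double KO replicate 4 (0.0668 to 0.15 without each of the other 8).

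Of 14 glutamatergic lineage members 7 fell against Dmrt5 KO, 9 when adjusted over the list alone, such as Neurod2 (log2 -3.60), Slc17a7 (-2.69), Nhlh1 (-1.99) and Neurod1 (-1.84). Their median was -1.06 (adjusted p = 1.76e-55, and 0.00036 with an estimated correlation). Of 14 pallial progenitor members 6 fell, 9 when adjusted over the list alone (median -0.46, adjusted p = 2.42e-47, and 2.27e-06 with an estimated correlation). Of 17 hem members 3 fell (Wnt3a, Rspo2 and Rspo3), 8 when adjusted over the list alone (median -0.86, adjusted p = 1.12e-22, and 0.0196 with an estimated correlation). No subpallial member was called over all genes by edgeR, and 5 of 20 rose when adjusted over the list alone. The subpallial median was 0.48 (adjusted p = 6.52e-13, and 0.0301 with an estimated correlation), with Dlx2 at 0.53, Gsx2 at 0.52 and Six3 at 0.48 on the log2 scale (adjusted p 0.521, 0.857 and 0.158). No choroid plexus member was called over all genes and 4 fell when adjusted over the list alone (median -0.67, adjusted p = 2.96e-06, and 0.0242 with an estimated correlation). Lhx2 (-0.47) and Lmx1a (-1.10) had adjusted p of 0.127 and 0.0511, and Dmrta2 of 0.19 (-1.58 ± 0.41). Lmx1a passed without double KO replicate 4 (-1.36, 0.00201), and Dmrta2 was -0.74 without Dmrt5 KO replicate 1 (adjusted p = 0.884). Medians of lists not kept were -0.28 for Wnt targets (adjusted p = 2.07e-05; adjusted p = 0.243 with an estimated correlation) and -0.38 for endothelium (5.42e-05; adjusted p = 0.243 with an estimated correlation). Sp5, a Wnt target, fell by 2.02 on the log2 scale, but not without Dmrt5 KO replicates 4 or 5 or double KO replicates 1 or 2 (0.0617 to 0.0839). The medial ganglionic eminence list had a median of 0.40 (0.0415; adjusted p = 0.451 with an estimated correlation; 0.0647 to 0.255 without Dmrt5 KO replicates 2 or 4 or double KO replicates 1, 2 or 3), and erythroid genes of -0.50 (0.00201; adjusted p = 0.395 with an estimated correlation; 0.0577 to 0.0726 without Dmrt5 KO replicate 2 or double KO replicate 5). Mesenchyme had a median of -0.54 (0.000143; adjusted p = 0.406 with an estimated correlation), which became 0.25 without Dmrt5 KO replicate 4 (adjusted p = 0.0885). The antihem list had a median of 0.23 and a mean of -0.02 (adjusted p = 0.726), and passed without double KO replicate 5 (median 0.12, adjusted p = 0.0339). Without that library the Cajal-Retzius (median -0.13, adjusted p = 4.78e-06), diencephalon (-0.16, 0.00382) and rostral Fgf (0.12, 0.0471) lists passed too. With all libraries these had adjusted p of 0.0571, 0.111 and 0.51. The Cajal-Retzius and diencephalon lists also passed without Dmrt5 KO replicate 1 (adjusted p = 0.0275 each).

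Removing Dmrt5 in addition to Dmrt3 lowered pallial and midline genes and raised subpallial ones. Emx1 fell from 169 ± 38.5 CPM (n = 5) to 8.51 ± 2.86 (n = 5), 19.9-fold (log2 -4.31 ± 0.26, adjusted p = 2.8e-08), Neurog2 4.82-fold from 284 ± 33.8 CPM (adjusted p = 1.19e-07), and Wnt3a 42.8-fold from 8.06 ± 0.963 CPM (adjusted p = 1.88e-05; 163-fold without double KO replicate 4). Dlx2 rose 2.74-fold from 187 ± 41.3 CPM (adjusted p = 3.58e-05), Gsx2 by 1.30 and Isl1 by 1.53 on the log2 scale, and Sp8 by 1.17 (adjusted p = 0.00142). Over all genes 282 rose and 318 fell, 144 and 236 more than 2-fold, and 2819 had an unadjusted p under 0.05. The count of genes higher was 167, 180 and 175 without Dmrt3 KO replicates 1 and 5 and double KO replicate 5, and the counts were 555 and 882 without double KO replicate 4. They were 148 and 210 with only these 2 genotypes in the fit. With the mesenchyme score as a covariate 108 rose, and with the length slope 505 fell. DESeq2 called 505 higher. Of 20 subpallial members 17 rose, 18 when adjusted over the list alone (median 1.30, adjusted p = 1.44e-36, and 0.000576 with an estimated correlation). Of 14 pallial progenitor members 8 fell and 1 rose over all genes and when adjusted over the list alone (median -0.96, adjusted p = 6.2e-33, and 3.13e-05 with an estimated correlation), and of 14 glutamatergic members 8 fell, 9 when adjusted over the list alone (median -1.44, adjusted p = 4.23e-32, and 0.00262 with an estimated correlation). Medial ganglionic eminence, hem and choroid plexus lists had medians of 1.5, -1.5 and -3.36 (adjusted p 0.0407, 0.00639 and 0.00027 with an estimated correlation). Wnt targets had a median of -0.61, with adjusted p = 4.83e-08 and adjusted p = 0.0777 with an estimated correlation. The rostral Fgf, eye, mesenchyme, endothelium, microglia, erythroid and immediate early lists passed at the preset correlation (0.000162 to 0.0477) and had adjusted p = 0.146 to 0.326 with an estimated correlation. The eye list had a median of 0.10 but a mean of -0.35 and was called lower, while the Cajal-Retzius list (median 0.02, mean -0.11) was not called (0.341), but was without double KO replicate 5 (median -0.10, adjusted p = 0.0144). The eye call was lost without Dmrt3 KO replicate 5 or double KO replicate 1, and its median became -0.06 and -0.31 without Dmrt3 KO replicate 2 and double KO replicate 4; the immediate early call was lost without Dmrt3 KO replicates 1 or 3 or double KO replicates 1 or 5 (adjusted p up to 0.0904 and 0.125). The Pax6 rise (log2 0.62, adjusted p = 0.0168) was lost without Dmrt3 KO replicates 1 or 5 (0.0507 to 0.0511), and the Wnt8b fall (log2 -1.26, adjusted p = 0.019) without Dmrt3 KO replicate 3 or double KO replicates 2 or 3 (0.0512 to 0.0552).

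The interaction tested whether the double KO differed from the sum of both single KO effects. Emx1 lay below additivity by a log2 interaction of -3.26 ± 0.35 (SE, adjusted p = 0.000328), Neurog2 by -2.05 ± 0.23 (0.000328), Eomes by -1.87 ± 0.24 (0.00107) and Neurod6 by -5.16 ± 0.78 (0.00554), or -6.13 without double KO replicate 1. Tfap2c (-1.76 ± 0.23, 0.00134), Dbx1 (-2.11 ± 0.31, 0.00554), Nhlh1 (-2.06 ± 0.21, 0.000235), Slc17a7 (-2.76 ± 0.32, 0.000465), Neurod1 (-1.95 ± 0.27, 0.00286) and Neurod2 (-3.76 ± 0.58, 0.00595) lay below additivity too. Over all genes edgeR called 23 below and 0 above additivity, all 23 by more than 1 on the log2 scale, with 1497 genes at an unadjusted p under 0.05; DESeq2 called 61 below and 66 above. With edgeR these counts were 35 and 1 with the length slope as a covariate. The count below was 15 without Dmrt3 KO replicate 3 or Dmrt5 KO replicates 1 or 5, and the count above was 7 without WT replicate 2 and 1 without double KO replicate 4. Of 14 glutamatergic members 6 lay below additivity, with 8 below and 1 above when adjusted over the list alone (median -1.18, adjusted p = 4.54e-23, and 0.017 with an estimated correlation). Of 14 pallial progenitor members 4 lay below, 6 when adjusted over the list alone (median -0.48, adjusted p = 9.91e-16, and 0.00146 with an estimated correlation). Subpallial regulators did not pass, with Gsx2 at 0.42 and Six3 at 0.34 (adjusted p 0.615 and 0.54); their list had a median of 0.30 (0.00788; adjusted p = 0.653 with an estimated correlation), and 0.0932 to 0.112 without WT replicate 3 or double KO replicate 2. Hem genes had a median of -0.57 (9.75e-05; adjusted p = 0.504 with an estimated correlation), with Wnt3a at -3.52 ± 0.75 (adjusted p = 0.106), and at -5.46 and called without double KO replicate 4 (0.00023). Lhx2 (-0.14, 0.716) and Emx2 (-0.63, 0.529) were not called. Choroid plexus, diencephalon, microglia, endothelium and mesenchyme lists passed at the preset correlation (0.00788 to 0.0468) and had adjusted p = 0.405 to 0.713 with an estimated correlation. The choroid plexus call was lost without WT replicate 2 (0.144), the diencephalon call without WT replicate 2 or Dmrt3 KO replicate 2 (0.0599 to 0.0908), and the endothelium call without WT 2 or 3, Dmrt3 KO 4 or 5, Dmrt5 KO 4 or double KO 1, 2, 3 or 5 (up to 0.18). The mesenchyme call was lost without any of these 9 libraries and without WT 1 or Dmrt3 KO 3 (up to 0.54). Median, mean and test differed in sign for the Cajal-Retzius, antihem and Notch lists, which were not called (adjusted p 0.721, 0.522 and 0.461). Tfap2e had an interaction of -3.21 ± 0.52 (adjusted p = 0.00904). The call of Neurog1 (-1.77, adjusted p = 0.0265) was lost without any of 10 libraries (WT 1, 3 and 4, Dmrt3 KO 1, 3 and 4, Dmrt5 KO 1, 4 and 5, and double KO 2; 0.0549 to 0.0876).

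Shared calls were counted between the comparisons against WT. Of the genes higher in Dmrt5 KO 53 of 55 were also higher in the double KO, where independent calls would share 1.33, and of the genes lower 109 of 112, where independent calls would share 4.27. Because both comparisons use the same WT libraries, they were also computed with 2 WT libraries each, which shared 1 to 31 genes higher and 17 to 108 lower over the 3 divisions. With fewer WT libraries a comparison can also call fewer genes, and the calls of each divided comparison were not counted. These numbers therefore do not separate the smaller number of libraries from the removal of shared WT libraries. Across genes, which are not independent replicates, log2 fold changes of Dmrt5 KO and double KO had a correlation of 0.79, against 0.52 in the simulations and 0.03 to 0.70 with the WT libraries divided. For Dmrt3 KO and Dmrt5 KO the correlation across genes was 0.66, against 0.53 simulated and -0.19 to 0.44 with divided WT libraries, and for Dmrt3 KO and the double KO 0.45, against 0.55 simulated and -0.23 to 0.42. These 3 correlations have no p-value. Genes in the simulations varied independently of each other, without the gradients between libraries described below. The simulated values are therefore an incomplete reference for correlations in the absence of change. The single gene called lower in both Dmrt3 KO and the double KO was Dmrt3.

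**Figure D4:**
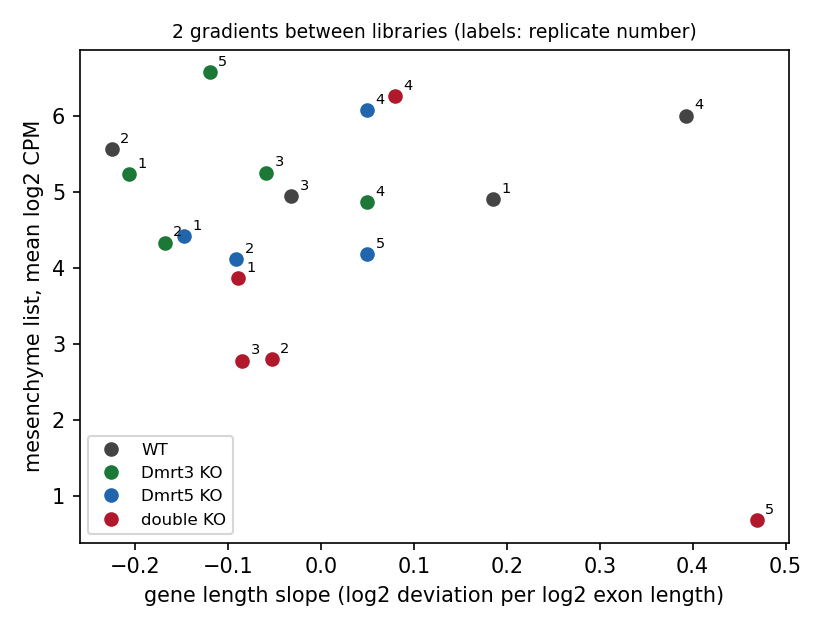
Each of the 18 libraries by its slope of expression against gene length (x axis) and its mesenchyme score (y axis, mean log2 CPM of the mesenchyme list), coloured by genotype. Double KO libraries run from 0.68 to 6.26 in mesenchyme score, and the slopes of WT replicate 4 and double KO replicate 5 are 0.393 and 0.469.

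Libraries of 1 genotype differed along both gradients drawn in the plot of length slope against mesenchyme score. After removal of genotype means, the first component of the residuals held 42.2% of the variance and its gene loadings followed gene length (Spearman 0.65 across 13071 genes, which are not independent). The second held 24.2% and followed the mesenchyme score. Mean mesenchyme scores were 5.35 ± 0.53 in WT, 5.25 ± 0.83 in Dmrt3 KO, 4.69 ± 0.93 in Dmrt5 KO and 3.28 ± 2.03 in the double KO (SD, log2 CPM). With the mesenchyme score as a covariate, chosen after seeing the data, some named genes were no longer called in the double KO against WT. Nkx2-1 went from a log2 fold change of 2 ± 0.46 (SE) to 1.64 ± 0.49, Lhx6 from 1.84 ± 0.40 to 1.2 ± 0.38 and Lef1 from -1.23 ± 0.26 to -0.87 ± 0.24 (adjusted p 0.0977, 0.117 and 0.067 with the covariate). Shh went from 1.95 ± 0.44 to 1.51 ± 0.45, Lhx5 from 1.07 ± 0.23 to 0.9 ± 0.25 and Sp8 from 0.77 ± 0.21 to 0.6 ± 0.24 (adjusted p 0.0951, 0.0691 and 0.304). These values kept their direction and most of their size, so the lost calls do not show that the mesenchyme gradient accounts for them. Calls of Dll3, Cdkn1a, Gbx2, Krt8, Krt18, Dusp1 and Egr1 were lost too, with log2 fold changes of 0.51, -0.75, 1.27, -1.12, -1.11, 0.36 and -0.64 with the covariate (adjusted p 0.127 to 0.385).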

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

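The tests on tissue shares, on the gene length and mesenchyme gradients and on Dmrt1 were chosen only after the result was seen; the test on the libraries with transcripts of both sexes and the counts of splits were planned before their results, and the count with the length covariate after the others were seen.

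The interaction between both knockouts was larger than the spread between libraries for 16 named genes. Values on the log2 scale were -5.16 for Neurod6, -3.76 for Neurod2, -3.32 for Cldn1, -3.26 for Emx1, -3.21 for Tfap2e, -2.94 for Sv2b, -2.76 for Slc17a7, -2.21 for Ism2, -2.11 for Dbx1, -2.06 for Nhlh1, -2.05 for Neurog2, -1.95 for Neurod1, -1.87 for Eomes, -1.77 for Neurog1, -1.76 for Tfap2c and -1.50 for Dmrt1. Calls of Cldn1, Sv2b, Ism2 and Neurog1 were each lost without any of several single libraries (adjusted p 0.0504 to 0.0993 over them). Neurod6 was -6.13 without double KO replicate 1 and Cldn1 -4.09 without double KO replicate 4. Of 100 splits that exchanged Dmrt3 status among libraries of the same Dmrt5 status, 1, the real one, gave as many as its 23 genes (highest other 1). Such splits remove every effect of Dmrt3, not only the departure from additivity, and mix Dmrt5 KO with double KO libraries. They therefore do not decide whether chance gave the interaction.

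The first pattern weighed is the fall of pallial and rise of subpallial genes in the double KO against WT. If a smaller share of pallial tissue in the dissected pieces were the whole cause, genes restricted to the pallium would fall by a common factor. Of the 18 called pallial and glutamatergic members 17 fell, with log2 fold changes from -5.66 to -0.873, and Pax6 rose by 0.85, which a smaller pallial share would give only if other tissue held more of it; the SD over the 18 was 1.5, above their median SE of 0.18, but members with transcript outside the pallium would fall less and 1 gene decides nothing for the set, so that share stays open for the falls. The 17 called subpallial members rose by 0.893 to 1.83 on the log2 scale with an SD of 0.31, near their median SE of 0.24. Only called members entered this SD, which narrows it. Members not called were Ebf1 (0.66), Zfp503 (0.44) and Rarb (-0.14). The SD therefore does not decide whether they rose by a common factor. A larger share of subpallial tissue stays open beside a change of gene expression within cells. With length slope and mesenchyme score as covariates 38 of 40 members kept call and sign, Pax6 among them (these 35 and 5 called members of the medial ganglionic eminence list, of which Lhx6 went from 1.84 ± 0.40 SE to 1.12 ± 0.36 and Shh from 1.95 ± 0.44 to 1.36 ± 0.41 and lost their calls, adjusted p 0.0736 and 0.0554, by smaller values at similar SE), with medians going from 1.61 to 1.18 for the subpallial and from -2.01 to -2.12 for the 17 pallial members that fell, which argues against these gradients as the whole cause.

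For the called counts, splits of the libraries gave these results. In the double KO against WT 7 of 100 splits called as many as the real 1012 genes, the highest other 5409, so chance cannot be excluded for this count. The largest count came from putting WT 1, 3 and 4 with double KO 4 and 5 against WT 2 with double KO 1 to 3. This split divides the libraries by length slope, with -0.225 to -0.053 in WT 2 and double KO 1 to 3 and -0.032 to 0.469 in the others. The count thus points to a structure of the samples along that slope. With the length slope as a covariate 3 of 100 splits reached the 2295 genes called (highest other 4960). The split with 4960 set all 4 WT libraries with double KO 4 against double KO 1, 2, 3 and 5, so it keeps most of the genotype contrast. For Dmrt3 KO against WT 1 of 100 splits gave the 2 genes (highest other 1), but 1 of the 2 is Dmrt3, which the design itself lowers, so this count does not decide whether chance gave Dmrt1. For Dmrt5 KO against WT 1 of 35 splits, the real one, reached the 167 genes (highest other 0). For the double KO 3 of 100 splits reached the 54 genes against Dmrt5 KO (highest other 114). Against Dmrt3 KO 2 of 100 reached the 600 genes (highest other 1393). In the last 2 a different split called more, and it grouped double KO replicate 4 with libraries of the other genotype. Against Dmrt5 KO it set all 4 Dmrt5 KO libraries with double KO 4 against double KO 1, 2, 3 and 5. Against Dmrt3 KO it only exchanged double KO 4 and Dmrt3 KO 2. Both keep most of the genotype contrast, so their larger counts do not stand for groupings unrelated to genotype. Apart from 7 of 100, the shares of splits given here were low but not adjusted over the comparisons, so they do not exclude chance.

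The second pattern is transcripts of both sexes in 2 libraries. WT replicate 2, which carries Xist, held 13 CPM of Y-linked transcripts, where the other 7 female libraries held at most 0.77, and Dmrt5 KO replicate 1, which is male, held 25.4 CPM of Xist, where the other 9 male libraries held at most 1.49. An exchange of RNA or reads between them could give Dmrt5 KO replicate 1 the 25.1 CPM of Dmrta2 that set it apart (8.92% of WT 2 once the mean of the other 3 Dmrt5 KO libraries is subtracted from both). Without subtraction Xist stood at 5.76% of WT 2, and Y-linked transcripts in WT 2 at 12.3% of Dmrt5 KO 1. Across 126 genes called without both libraries, Dmrt5 KO replicate 1 was shifted towards WT by 1.97% (95% interval -4.38 to 5.76, 2000 bootstraps over genes). An interval including 0 had been set beforehand to exclude an exchange, but that bound was wrong. The other Dmrt5 KO libraries shift by -12.4% (replicate 2), 7.96% (replicate 4) and 5.47% (replicate 5) on the same measure, a spread wider than that interval. The shift is also a share of a log2 distance, towards the mean of WT 1, 3 and 4. It can therefore not be set against the share for Xist, which is a ratio of CPM to WT 2. An exchange, RNA of other embryos or pooled embryos thus stay open.

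The third pattern is Dmrt1, which rose by 1.73 on the log2 scale in Dmrt3 KO. If DNA of the targeted Dmrt3 allele acted on its neighbour in cis, Dmrt1 would be as high in the double KO. There its log2 fold change against WT was -0.11, with an interaction of -1.50 ± 0.27, which would argue against an effect in cis if both genotypes carried the same Dmrt3 allele and the same DNA around it. The labels do not state this. Within 5 Mb of Dmrt3 10 of 53 genes were called in the double KO against WT (Fisher's exact p = 0.00141), and 1, Dmrt1, in Dmrt3 KO. These counts say little beside each other, since 1012 genes were called over all genes in the double KO and 2 in Dmrt3 KO. Of the 10 genes, 7 had values below WT in Dmrt3 KO and 8 in Dmrt5 KO. An effect in cis therefore stays open, beside a requirement for Dmrt5 in the rise, which these data suggest without testing it apart from other differences between the genotypes.

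Some libraries lay far from the others of their genotype; chance does so in about 1 in 20 groups, and 13 of 156 groups tested did. Scores are mean log2 CPM of a list. Double KO replicate 4 had 2.9 for the cortical hem (others 0.54 to 0.92), 3.95 for Wnt targets (2.59 to 2.87) and 0.72 CPM of Wnt3a (0 to 0.1). Double KO replicate 5 had 5.08 for Cajal-Retzius genes (4.23 to 4.39), 5.22 for erythroid genes (6.69 to 7.08) and 459 CPM of Pax6 (275 to 290). WT replicate 2 had 2.64 for choroid plexus (3.77 to 3.96) and 4.97 for rostral Fgf genes (4.09 to 4.24), and WT replicate 4 had 256 CPM of Gli3 (177 to 181). Dmrt5 KO replicate 4 had 6.07 for mesenchyme (4.11 to 4.42), Dmrt5 KO replicate 1 had 106 CPM of Emx1 (59.2 to 65.2) and 25.1 of Dmrta2 (4.31 to 6.94), and Dmrt3 KO replicate 1 had 236 CPM of Emx1 (143 to 164).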

How the results depend on the processing

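The fits with length slope or mesenchyme score as covariates, without the 2 libraries carrying transcripts of both sexes and without the library highest in mesenchyme of each genotype were chosen only after the results were seen. Of 202 calls of named genes, 156 held without each single library and 134 in every setting; of 4786 values of these genes under other settings 4312 kept call and direction, 474 kept direction only and 0 reversed. RLE normalisation and the filter of 1 CPM in 4 libraries kept all 12 counts within 1.5 times, as did the counts not printed here under the other settings. Where a count changed by more, the cause was not tested, except that stricter thresholds call fewer genes by construction. DESeq2 called 53 genes lower in Dmrt3 KO against WT, 210 higher and 228 lower in Dmrt5 KO, 656 higher in the double KO, 13 higher and 99 lower in the double KO against Dmrt5 KO, 505 higher against Dmrt3 KO, and 66 above and 61 below additivity. Without a filter 31 were higher in Dmrt5 KO and 1 in the double KO against Dmrt5 KO. With only the genotypes compared in the fit 2 were lower in Dmrt3 KO, 52 lower in Dmrt5 KO, 131 higher and 237 lower in the double KO, 19 lower against Dmrt5 KO, and 148 higher and 210 lower against Dmrt3 KO. Replicate number as a block gave 2 lower in Dmrt3 KO, 184 higher and 196 lower in Dmrt5 KO and 1 higher against Dmrt5 KO; residuals of the 24 pairs with the same number had correlations across genes of -0.357 to 0.703 (15 over 0.1; median 0.24, against -0.14 for 97 other pairs) and 4 libraries were closest to their own number. Not every pair was over 0.1, so the numbers were not taken as pairs; some shared structure between them is not excluded. Sex as a factor gave 97 higher in Dmrt5 KO and 1 higher against Dmrt5 KO. An adjusted p under 0.01 gave 8 higher and 38 lower in Dmrt5 KO, 183 and 327 in the double KO, 1 and 30 against Dmrt5 KO, 117 and 185 against Dmrt3 KO, and 15 below additivity. The test against a 1.2-fold change gave 18 higher in Dmrt5 KO, 222 in the double KO, 1 against Dmrt5 KO and 156 against Dmrt3 KO. The length slope gave 2 higher and 51 lower in Dmrt3 KO, 215 and 276 in Dmrt5 KO, 1052 and 1243 in the double KO, 7 and 102 against Dmrt5 KO, 505 lower against Dmrt3 KO, and 1 above and 35 below additivity. The mesenchyme score gave 145 higher and 330 lower in the double KO, 1 higher against Dmrt5 KO and 108 higher against Dmrt3 KO. Both gave 5 higher and 82 lower in Dmrt3 KO, 252 and 367 in Dmrt5 KO, 9 and 125 against Dmrt5 KO, and 1 above and 58 below additivity. Without the 2 libraries carrying transcripts of both sexes 3 were lower in Dmrt3 KO, 27 higher in Dmrt5 KO and 1 higher against Dmrt5 KO. Without the library highest in mesenchyme of each genotype (scores 6, 6.57, 6.07 and 6.26) 26 were higher in Dmrt5 KO, 656 higher and 1143 lower in the double KO, 1 higher against Dmrt5 KO and 709 lower against Dmrt3 KO.

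With each library left out in turn, the range was 1 to 1 higher and 1 to 5 lower in Dmrt3 KO, 14 to 55 and 40 to 170 in Dmrt5 KO, 252 to 734 and 465 to 1272 in the double KO, 1 to 5 and 33 to 74 against Dmrt5 KO, 167 to 555 and 229 to 882 against Dmrt3 KO, and 0 to 7 above and 15 to 31 below additivity. List medians that changed sign were Cajal-Retzius in the double KO (-0.21 to 0.08; negative without WT 2, at -0.10, and double KO 5) and against Dmrt3 KO (-0.10 without double KO 5, up to 0.12), eye against Dmrt3 KO (-0.31 without double KO 4, -0.06 without Dmrt3 KO 2, up to 0.48), and mesenchyme against Dmrt5 KO (0.25 without Dmrt5 KO 4, down to -2.21) and in the interaction (0.28 without Dmrt5 KO 4, 0.07 without Dmrt3 KO 5, down to -2.09). The cause was not tested. For shared higher calls, Dmrt5 KO vs WT and double KO vs WT, the numbers were 8 at 0.01, 186 with DESeq2 and a mean of 9 with WT divided. For shared lower calls, Dmrt5 KO vs WT and double KO vs WT, they were 38, 207 and 48, and the correlation was 0.43 with WT divided. For Dmrt3 KO DESeq2 shared 38 lower with the double KO and 11 with Dmrt5 KO (2.8 and 0.2, and correlations of 0.15 and 0.21, with WT divided). Depth of 19602718 to 33072896 counts limits genes near 0, such as Wnt3a in the double KO (0 to 0.72 CPM).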

Other observations

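The tests on genes of motile cilia and on neighbours of the targeted genes were chosen only after the result was seen.

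Among the genes that fell without Dmrt5 were 4 linked to the formation of many motile cilia, picked after their values were seen. Mcidas stood at 8 ± 2.38 CPM in WT (SD, n = 4), 6.44 ± 1.29 in Dmrt3 KO (n = 5), 1.58 ± 0.533 in Dmrt5 KO (n = 4) and 0.355 ± 0.284 in the double KO (n = 5), and fell 22.1-fold in the double KO against WT (log2 -4.47 ± 0.43 SE, adjusted p = 4.86e-06). Ccno went through 17.2 ± 3.5, 15.5 ± 2.51, 3.9 ± 0.868 and 0.837 ± 0.691 CPM in the same order, and Gmnc through 10.8 ± 5.11, 6.8 ± 2.35, 1.49 ± 0.66 and 0.138 ± 0.216. Foxj1 stood at 45 ± 8.54, 49.9 ± 10.2, 20 ± 4.06 and 14.9 ± 3.61 CPM. In the double KO against WT Ccno, Gmnc and Foxj1 had log2 fold changes of -4.35, -6.22 and -1.59 (adjusted p 4.5e-06, 1.43e-05 and 0.000109); Gmnc had -7.78 without double KO replicate 4. In Dmrt5 KO Mcidas, Ccno, Gmnc and Foxj1 had -2.34, -2.14, -2.86 and -1.17 (adjusted p 0.00852, 0.0124, 0.0184 and 0.0121). There the Gmnc call was lost without WT replicate 4 or Dmrt5 KO replicates 1, 2 or 5 (0.062 to 0.0968) and the Foxj1 call without Dmrt5 KO replicate 2 (0.0613). Mcidas and Ccno were not recomputed there without single libraries. Of 53 axonemal genes picked by symbol prefix, 6 fell in Dmrt5 KO (Cfap52, Drc7, Rsph4a, Cfap54, Dnah6 and Cfap65) and 12 in the double KO, with none higher by edgeR in either. Their median log2 fold change was -0.50 in Dmrt5 KO (camera p = 1.39e-11, and p = 0.00282 with an estimated correlation) and -0.30 in the double KO (p = 3.33e-07, and p = 0.0166 with an estimated correlation). In Dmrt3 KO none was called and the estimated-correlation p was 0.437, and for the interaction it was 0.591. Against Dmrt3 KO 10 fell in the double KO (median -0.24, camera p = 0.0311 with an estimated correlation). Against Dmrt5 KO no axonemal gene was called in the double KO (median 0.004, camera p = 0.875 with an estimated correlation). There Gmnc fell 10.2-fold (adjusted p = 0.0357), and Foxj1 was not called (log2 -0.42, adjusted p = 0.997). The falls are consistent with fewer multiciliated cells of the midline and choroid plexus; a lower share of that tissue in the pieces was not told apart from it.

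Genes within 5 Mb of the targeted genes were compared with all others by 10 two-sided Fisher's exact tests, and genes near each other are not independent. Near Dmrta2, 2 of 66 genes were called in Dmrt5 KO against 163 of 16170 others (odds ratio 3.07, exact p = 0.145), so DNA linked to the targeted allele could contribute to these calls and stays open. In the double KO 6 of 66 were called there (exact p = 0.304), and in Dmrt3 KO exact p = 1. Near Dmrt3, 10 of 53 were called in the double KO against WT, and 1001 of 16183 others (odds ratio 3.53, exact p = 0.00141), and 1 in Dmrt5 KO (exact p = 0.42). In Dmrt3 KO Dmrt1 was the 1 gene called there, and since it prompted the test its p is not used. Against Dmrt3 KO 4 of 52 were called in the double KO with Dmrt1 left out (odds ratio 2.18, exact p = 0.125), and none by edgeR against Dmrt5 KO (52 of 16183 others, exact p = 1). DNA linked to the targeted Dmrt3 allele could thus contribute to the calls in the double KO. It stays open beside loss of Dmrt5, since 8 of the 10 genes had values below WT in Dmrt5 KO and 7 in Dmrt3 KO. In Dmrt5 KO Ptar1 was called (log2 -0.98). Not called there were Trpm3 (-1.93), Mamdc2 (-1.53) and 1700028P14Rik (-1.78), and above WT were Fam189a2 (0.45) and Vldlr (0.29). The others, Gm9493, Gm6563, Gm8825 and Gm5822, carry symbols of predicted genes. Their counts are uncertain where pseudogenes or close paralogs share reads. Near Dmrta2 the double KO had 3 of 66 called against Dmrt3 KO (exact p = 0.736) and none by edgeR against Dmrt5 KO (exact p = 1).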
